A study of Zea mays with 6 samples.

How the data were processed

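The series holds RNA-seq of 3 tissues of the maize inbred line Q319: unpollinated embryo sacs, the nucellus around them, and embryo sacs taken 14 to 16 h after pollination. The embryo sac is the female gametophyte, which carries the egg cell, and the nucellus is the maternal ovule tissue that encloses it. Per the labels' protocols, embryo sacs and nucellus were separated by enzyme treatment of ovule slices, RNA was purified with poly(A) selection, Illumina libraries were made, and each tissue had 2 biological replicates. Samples were grouped by the tissue named in the labels, 2 libraries in each of 3 groups.

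Each library has its own deposited table of unique read counts per transcript model, per the file headers. The counts are whole numbers, they sum to the total stated in the header, and models without a read are not listed, so a model missing from a table was taken as 0. The deposited RPKM values are the count scaled to model length and to the total of unique reads, and recomputing them from count, length and total gave a largest relative difference of 1.39e-08. The aligner, the counting tool and the genome build are not given in the sources used here. Values are per transcript model: 42007 models of 31057 genes were listed in any library, 8024 genes had more than 1 model, and those genes held 15.5% of the reads. The number of models of a gene covers only models listed in at least 1 library. A gene with 1 model here may therefore have further models that drew no read. Because only unique reads were counted, reads shared by models of a gene or by near-identical copies are missing or split, and the level of such models is uncertain. The files give no strand information, so reads of overlapping antisense genes cannot be separated.

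Protein descriptions come from the deposited tables. For models shared by tables, the GO process text was identical among the 4 unpollinated embryo sac and nucellus tables and between both pollinated tables, and differed for 9.30% to 9.53% of models between these sets, with equal model lengths. An informative description was present for 8358 models (19.9%), which held 21.0% of the reads, so statements on gene groups cover that part of the transcriptome. Gene symbols were looked up in a reference gene table of assembly Zm-B73-REFERENCE-NAM-5.0, which matched 17131 genes (55.2%). This table was used for names only, and no coordinates are given.

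Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalisation, robust quasi-likelihood fit). All 6 libraries entered one fit, so that the 3 groups shared one estimate of the spread. The filter left 18844 models. A model was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Levels are CPM (the edgeR cpm function) on TMM-scaled library sizes, as mean ± SD of 2 libraries, and log2 fold changes are given ± SE. TMM factors were 0.874 and 0.878 for embryo sac, 1.48 and 1.47 for nucellus, and 0.782 and 0.768 for pollinated embryo sac. Without these factors the median log2 change of all tested models moved from -0.00 to -0.75 for embryo sac against nucellus, from -0.08 to -0.26 for pollinated against unpollinated embryo sac, and from -0.06 to -0.99 for pollinated embryo sac against nucellus, so all changes are relative to the bulk of the transcriptome.

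Totals of 2.54e+06 to 3.26e+06 reads per library set the precision. Where the lower group had no read, the fold is a lower bound against 3 counts per library, which is 0.650 to 1.52 CPM. Where it had 1 to 3 reads in all, the ratio is given with its 95% interval for counting error. Intervals and bounds cover counting error only, since reads amplified by PCR are not independent molecules. The procedure was tested on simulated data drawn from the real library sizes and dispersions, with the mean of each model pooled over the 2 groups compared. Few models were then changed, up or down at random (94 and 93 at the 2 sizes for embryo sac against nucellus). The simulation therefore does not cover the shift in scaling between the real groups, nor false calls that it may cause. For embryo sac against nucellus, with 16876 models, it recovered 85.1% of models changed by 1.5 on the log2 scale and 97.8% of those changed by 3, with 1 false call among 172. For pollinated against unpollinated embryo sac, with 18043 models, recovery was 73.2% and 86.6%, with 2 false calls among 157.

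A set of 27 gene lists, made of search terms for the descriptions, was fixed before the data were examined, and so was the rule for named models. The rule takes, for each of the first 2 comparisons, the 6 called models with the largest change in each direction that had an informative description, at least 10 CPM in the higher group and both libraries beyond both of the other group. It also takes the called member of each list with the smallest p in each direction, and all known embryo sac genes. A part of the models so chosen is named in the text. Some terms had matched inside longer words, such as sperm in endosperm, and these matches were removed after the data were seen: 33 of 46 models of the defensin-like list, 8 of 13 of the RWP-RK list and 14 of 73 of the pollen list. Lists with at least 5 tested members, 25 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Gene Ontology process terms of the deposited tables with 15 to 500 tested models were added after the data were seen and tested with one-sided Fisher's exact tests.

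Alternatives were RLE size factors, the DESeq2 1.42.0 Wald test, no count filter, limma on log2(RPKM + 1) or log2(RPKM + 0.1), the replicate number as a block, only the 2 groups compared, adjusted p alone, and leaving out each library. Total count scaling, counts summed per gene, genes with 1 model only, and the lists as first matched were added after the data were seen. Groups of 2 libraries allow neither a test for outlying libraries nor a count over other groupings. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.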

Results

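Transcript levels were measured by RNA-seq in unpollinated embryo sacs, nucellus and embryo sacs 14 to 16 h after pollination, with 2 libraries per tissue. The embryo sac libraries listed 31193 and 30963 transcript models with unique reads, the nucellus libraries 32780 and 33296, and the pollinated libraries 26859 and 26734. Libraries of one tissue had a Pearson correlation of log2(CPM + 1) of 0.979 for embryo sac, 0.983 for nucellus and 0.981 for pollinated embryo sac. Here CPM was scaled to total reads without TMM, over all 42007 models listed in any library, including those without a read in either library. Their counts differed by more than sampling noise, with a chi-square per degree of freedom of 2.13, 1.93 and 1.89, and the labels name them biological replicates. This ratio alone does not separate biological from library preparation differences. The first principal component held 75.2% of the variance and separated nucellus from both kinds of embryo sac, and the next held 19.8% and separated pollinated from unpollinated embryo sacs. The 10 most abundant models took 13.6% and 13.9% of the reads in embryo sac, 2.90% and 2.87% in nucellus, and 10.3% and 10.7% in pollinated embryo sac. At an RPKM of at least 1 in both libraries, 18014 models were detected in embryo sac, 20303 in nucellus and 15886 in pollinated embryo sac. Of these, 339, 2166 and 387 stayed below that level in every library of the other tissues.

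**Figure D1:**
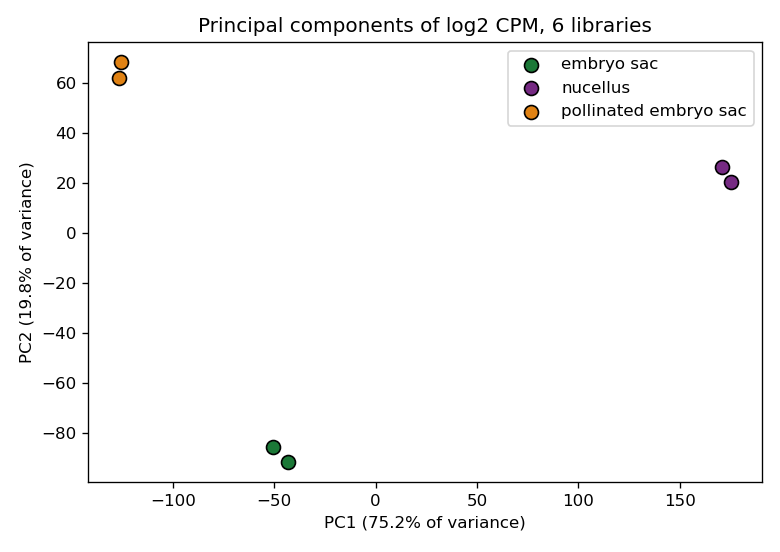
Principal components of log2 CPM of the 6 libraries, with the first component (75.2% of the variance) on the x axis and the next (19.8%) on the y axis. Each point is 1 library, and the 2 libraries of each tissue lie next to each other.

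Embryo sac was compared with nucellus to ask which transcripts the female gametophyte holds above the tissue around it. All 9 tested models of known embryo sac genes were higher in the embryo sac. EBE-2 (GRMZM2G167733_T02) stood at 1388 ± 50.7 CPM (SD, n = 2) against 0.229 ± 0.324 in nucellus, a ratio of 6223 with a counting interval of 1722 to 51390. A model described as ES2 precursor (GRMZM2G009359_T01), of the secreted cysteine-rich ES family, stood at 392 ± 39.2 CPM against no read in nucellus, at least 586-fold higher. MEG1 (GRMZM2G145466_T01), also a small cysteine-rich protein, was at least 1202-fold higher at 804 ± 59.9 CPM. Bearded-ear1 (GRMZM2G160565_T01), a MADS-box gene of ear development, had no read in the embryo sac libraries and 54.8 ± 10.4 CPM in nucellus, at least 49.6-fold lower in embryo sac.

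The remaining known embryo sac models ranged widely in level. Another EBE protein (GRMZM2G129157_T01) was higher by 5.66 ± 0.15 on the log2 scale at 693 ± 26.2 CPM, and an EGG APPARATUS-1 model (GRMZM2G157505_T01) was higher by 4.95 ± 0.17 at 215 ± 31.4 CPM. EGG APPARATUS-1 (ZmEA1) is a small secreted protein needed for pollen tube attraction in maize. The other model with that name (GRMZM2G456746_T01), of another gene, stood at 17.3 ± 0.867 CPM and was at least 25.9-fold higher. Of these models, only the description of GRMZM2G456746_T01 also gives the name ZmEA1. ES1 precursor (GRMZM2G012012_T01) was at least 138-fold higher, the other ES2 precursor model (GRMZM2G128301_T01) at least 84.8-fold, di-SUMO-like protein (GRMZM2G006324_T01) at least 92.7-fold, and the other model of the EBE-2 gene (GRMZM2G167733_T01) at least 18.9-fold. Another list member, LOB domain-containing protein 6 (GRMZM2G118250_T06), had 6 reads over all 6 libraries and was not tested. The list had a median log2 change of 10.45 as fitted and 6.41 with 6 members at their bound, and 9 of 9 were also called when adjusted over the list alone. Its camera test gave an adjusted p = 1.31e-06 (adjusted p = 0.328 with an estimated correlation). These genes were first described from embryo sacs, so the list also serves as a check of the tissue labels.

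**Figure D2:**
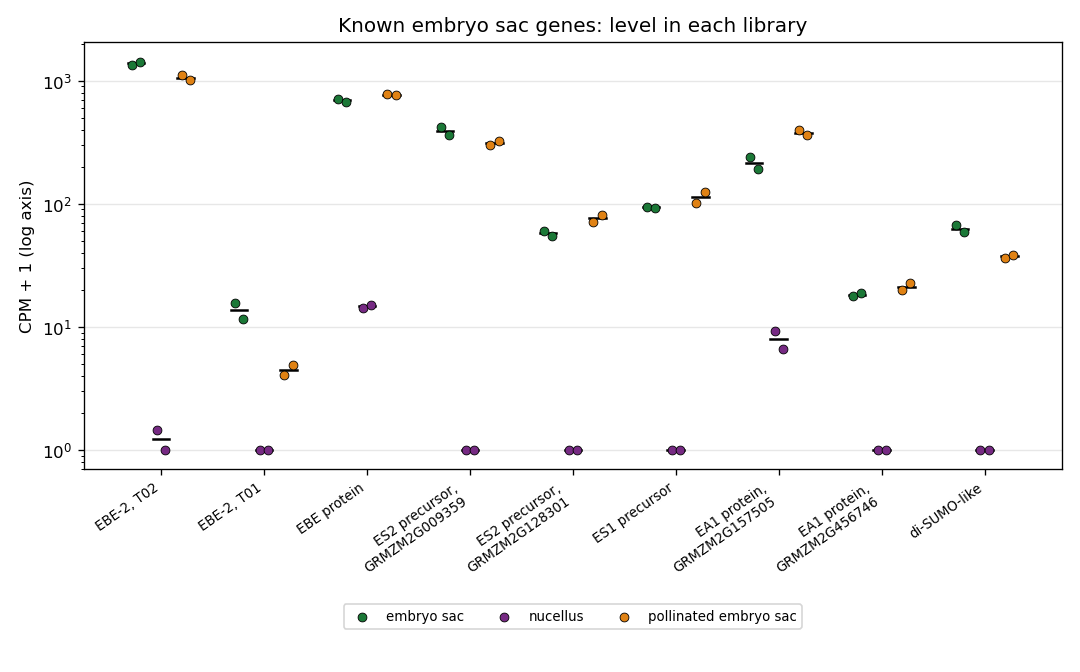
Level of the 9 tested known embryo sac models in each library, as CPM + 1 on a log axis. Points are libraries and black bars are means of 2 libraries. In nucellus, 6 of the models had no read and lie at 1, and the embryo sac libraries lie above the nucellus libraries for each model.

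Other abundant embryo sac transcripts were nearly missing from nucellus. A pair of esterase precursors stood at 666 ± 5.49 CPM (GRMZM2G123365_T01, at least 995-fold higher) and 324 ± 10.6 CPM (GRMZM2G046306_T01, at least 484-fold), and ae1 protein precursor (GRMZM2G112855_T01) at 295 ± 60.9 CPM (at least 441-fold). Peroxidase 1 precursor (GRMZM2G177792_T01) reached 2847 ± 80.3 CPM against 0.344 ± 0.486, a ratio of 8514 (2913 to 41290). A pectinesterase inhibitor (GRMZM2G457612_T01) stood at 952 ± 73.3 CPM with a ratio of 2855 (976 to 13850). The MADS-box protein AGL66 (GRMZM2G152415_T01) stood at 246 ± 16.7 CPM with a ratio of 734 (251 to 3562). A cysteine proteinase inhibitor (GRMZM2G041317_T01) was higher by 11.77 ± 0.22 on the log2 scale, with only 4 reads in nucellus. LCR70 (GRMZM2G380656_T01), the single tested member of the defensin-like list, was higher by 7.67 ± 0.18 at 846 ± 197 CPM.

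Models of the hormone list, made of search terms, went both ways, with more higher than lower in the embryo sac. Of 72 tested models of the ethylene, cytokinin, gibberellin and abscisic acid list, 35 were higher and 9 lower, the same counts as adjusted over the list alone, with camera adjusted p = 0.00839 (adjusted p = 0.328 with an estimated correlation). Cytokinin dehydrogenase 4 (GRMZM5G817173_T03), which degrades cytokinin, was higher by 7.81 ± 0.28, with only 4 reads in nucellus. The response regulator-like PRR95 (GRMZM2G367834_T01) was lower at -2.79 ± 0.19. PRR95 is on the list through the search term response regulator, and its description names no hormone. Of 11 models for sugar transport and sucrose cleavage, 7 were higher and none lower, also when adjusted over the list alone (camera adjusted p = 0.0293, and adjusted p = 0.328 with an estimated correlation). The invertase IVR1 (GRMZM2G394450_T01), which splits sucrose, was higher by 5.36 ± 0.29. In the nucellus degeneration and proteolysis list, 4 of 6 models were higher and none lower, also when adjusted over the list alone (camera adjusted p = 0.0084, and adjusted p = 0.337 with an estimated correlation). The list holds mostly cysteine proteases, and cysteine protease 1 (GRMZM2G340065_T01) stood at 1048 ± 66.9 CPM against 73.6 ± 11.4 in nucellus.

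Histone models were the one list lower in embryo sac past the threshold. Of 47 tested, 11 were lower and 5 higher, also when adjusted over the list alone, with camera adjusted p = 0.00839 (adjusted p = 0.541 with an estimated correlation). A histone H2B.3-like model (GRMZM2G119071_T01) was lower at -1.57 ± 0.11, and a histone H2A model (GRMZM2G107540_T01) was higher by 1.82 ± 0.24. Among single models lower in the embryo sac, the cytochrome P450s CYP71C3v2 (GRMZM2G063756_T01) and 71C1 (GRMZM2G172491_T01), of the family that makes benzoxazinoid defence compounds, stood at 143 ± 33.3 and 93.8 ± 28.8 CPM in nucellus against 0.355 ± 0.502 and 1.09 ± 0.466. The nucellus to embryo sac ratio of CYP71C3v2 was 390 (108 to 3224). On leaving out 1 library, the fitted log2 change ranged from -11.79 to -7.54 for CYP71C3v2, from 11.43 to 14.93 for EBE-2 (GRMZM2G167733_T02) and from 11.93 to 15.97 for peroxidase 1 precursor. DNA (cytosine-5)-methyltransferase 1 (GRMZM2G025592_T01, met2) was lower at -2.80 ± 0.14, MADS16 (GRMZM2G110153_T01) at -1.96 ± 0.15, and a chlorophyll a-b binding protein (AC207722.2_FGT009) at -4.39 ± 0.45 (-5.55 to -3.75 on leaving out 1 library). An ATP-binding cassette transporter (GRMZM2G177314_T01) was at least 24.9-fold lower, a protein binding protein (GRMZM2G342509_T01) at least 31.6-fold and early nodulin 20 precursor (GRMZM2G116632_T01) at least 11.8-fold.

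The other lists did not pass the camera test, and counts adjusted over the list alone equalled those over all models. Higher and lower members numbered 33 and 13 of 67 for cell wall remodelling (adjusted p = 0.0782), 29 and 10 of 65 for defence (adjusted p = 0.0882), 15 and 3 of 41 for heat shock proteins (adjusted p = 0.0941), 4 and 1 of 7 for storage proteins (adjusted p = 0.0941) and 28 and 9 of 71 for peroxidases and redox (adjusted p = 0.135). They numbered 2 and 7 of 17 for photosynthesis (adjusted p = 0.0782), 3 and 10 of 29 for DNA replication and cell cycle (adjusted p = 0.123), 4 and 16 of 146 for ribosomal proteins (adjusted p = 0.144) and 6 and 8 of 19 for MADS-box factors (adjusted p = 0.209). For pollen and pollen tube they numbered 3 and 4 of 14 (adjusted p = 0.558), for integument, epidermis and vascular tissue 9 and 2 of 16 (adjusted p = 0.683), and for jasmonate and wounding 10 and 8 of 23 (adjusted p = 0.497). Counts were 17 and 6 of 66 for vesicle trafficking (adjusted p = 0.167), 14 and 13 of 52 for receptor-like kinases (adjusted p = 0.522), 16 and 10 of 59 for auxin (adjusted p = 0.558), 12 and 10 of 43 for calcium signalling (adjusted p = 0.943) and 19 and 9 of 111 for proteasome, ubiquitin and F-box (adjusted p = 0.943). They were 4 and 3 of 8 for lipid transfer proteins (adjusted p = 0.354), 1 and 3 of 21 for RNA silencing and chromatin (adjusted p = 0.554) and 7 and 3 of 28 for transposable elements (adjusted p = 0.683). Of 2 tested RWP-RK models, 1 was lower. With total count scaling, the medians of 11 of the 25 lists changed sign, none of them in the 5 lists past the threshold. Median and mean differed in sign for MADS-box factors (-0.80 and 0.75), receptor-like kinases (-0.26 and 0.29), RNA silencing (0.03 and -0.30) and pollen (0.11 and -0.05), and the test pointed down against a positive median and mean for calcium signalling and for proteasome, ubiquitin and F-box.

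In all, 4368 models of 4209 genes were higher in the embryo sac and 3065 models of 2948 genes were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The models named here as higher or lower had adjusted p-values from 4.61e-105 to 3.18e-11 in this test, and both libraries of one tissue lay beyond both of the other. The split depended on the scaling: higher calls were 58.8% of all calls, against 28.7% with total count scaling (2996 higher and 7463 lower). With limma on log2(RPKM + 1), which also changed the test, the filter and the models tested (24492), they were 30.1% (3260 and 7553).

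Pollinated embryo sacs were compared with unpollinated ones to ask which transcripts differed 14 to 16 h after pollination. Flavonoid 3-monooxygenase (GRMZM2G125482_T01), an enzyme of flavonoid synthesis, rose from 1.99 ± 1.20 to 1333 ± 185 CPM (SD, n = 2), a log2 change of 9.34 ± 0.21 (8.86 to 10.14 on leaving out 1 library). It is a member of the integument, epidermis and vascular tissue list, which holds markers of other tissues. ACC oxidase (GRMZM2G072529_T01), the last enzyme of ethylene synthesis, rose from 0.381 ± 0.539 to 108 ± 7.70 CPM, a ratio of 294 (80.9 to 2436). LCR70 (GRMZM2G380656_T01) fell by 4.67 ± 0.15 to 33.2 ± 5.43 CPM and peroxidase 1 precursor (GRMZM2G177792_T01) fell by 3.69 ± 0.12 to 220 ± 15.5 CPM.

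The jasmonate and wounding list had the smallest camera adjusted p at the preset correlation, with 10 of 23 models higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 7.19e-05, and adjusted p = 0.131 with an estimated correlation). Over genes with 1 model, 4 of 14 members were higher and 0 lower. A lipoxygenase (GRMZM2G109130_T01, lox3), an enzyme that oxidises fatty acids and 1 of 2 models of its gene, rose by 3.29 ± 0.23. It is on the list through the search term lipoxygenase, and its description does not name jasmonate. The member that fell was a wound responsive protein (GRMZM2G006468_T05), 1 of 3 models of its gene, at -1.92 ± 0.45. In the defence list, 22 of 65 models were higher and 7 lower, also when adjusted over the list alone (camera adjusted p = 0.000467, and adjusted p = 0.131 with an estimated correlation). A WRKY transcription factor model (GRMZM2G158328_T01) rose by 4.47 ± 0.20 to 168 ± 22.9 CPM, and a trypsin inhibitor precursor (AC208221.3_FGT002) fell by 2.78 ± 0.26. The hormone list had 24 of 72 models higher and 11 lower, also when adjusted over the list alone (camera adjusted p = 0.00123, and adjusted p = 0.131 with an estimated correlation). Gibberellin 20 oxidase 2 (GRMZM2G099467_T01), of gibberellin synthesis, rose by 2.85 ± 0.13 to 394 ± 51.3 CPM. A pseudo-response regulator 37 model (GRMZM2G033962_T01), on the list through the search term response regulator and not a named hormone, fell by 2.40 ± 0.18.

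Cell wall remodelling models went both ways, with 24 of 67 higher and 13 lower, also when adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.199 with an estimated correlation). Alpha-expansin 15 (GRMZM2G105844_T01), a wall-loosening protein and 1 of 2 models of its gene, rose by 2.50 ± 0.12. Polygalacturonase precursor (GRMZM2G137077_T01), which cleaves pectin, fell by 2.60 ± 0.12 from 986 ± 9.16 to 163 ± 17.2 CPM. Ribosomal protein models passed the list test upward (camera adjusted p = 0.0124, and adjusted p = 0.47 with an estimated correlation), yet 14 of 146 were higher and 17 lower, also when adjusted over the list alone, and their median log2 change was 0.32 and their mean -0.01. The 60S acidic ribosomal protein P3 (GRMZM2G378770_T01) rose by 3.11 ± 0.29, and a 40S ribosomal protein S18 model (GRMZM2G389015_T04), 1 of 4 models of its gene, fell by 3.65 ± 0.36 (-4.899 to -2.996 on leaving out 1 library).

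The embryo sac markers changed little beside these genes. Of the 9 known embryo sac models, 1 was called, the EBE-2 model GRMZM2G167733_T01, 1 of 2 models of its gene, which fell by 1.85 ± 0.44. It was also called when adjusted over the list alone (camera adjusted p = 0.859 for the list, with a median of 0.15 and a mean of -0.16). The log2 changes of the other 8 lay between -0.77 for di-SUMO-like protein and 0.81 for the EGG APPARATUS-1 model GRMZM2G157505_T01, below the fold threshold. Some of these small changes still had an edgeR adjusted p under 0.05. It was 2.3e-10 for this EGG APPARATUS-1 model, 0.00027 for di-SUMO-like protein and 0.00073 for EBE-2 (GRMZM2G167733_T02, -0.39). For the ES2 models it was 0.0081 (GRMZM2G009359_T01, -0.33) and 0.032 (GRMZM2G128301_T01, 0.41). The other EGG APPARATUS-1 model (GRMZM2G456746_T01), described as ZmEA1, stood at 0.22 ± 0.27 (edgeR adjusted p = 0.515). The EBE protein (GRMZM2G129157_T01) stood at 0.15 ± 0.10, which turned to -0.03 with total count scaling. AGL66 (GRMZM2G152415_T01) fell by 1.80 ± 0.13. Among models with no read in nucellus, MEG1 (GRMZM2G145466_T01) fell by 2.34 ± 0.12 and ae1 protein precursor (GRMZM2G112855_T01) by 1.98 ± 0.13, while the esterase precursor GRMZM2G123365_T01 stood at 0.58 ± 0.10. These 3 were followed here because of their level in embryo sac, after their values had been seen.

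**Figure D3:**
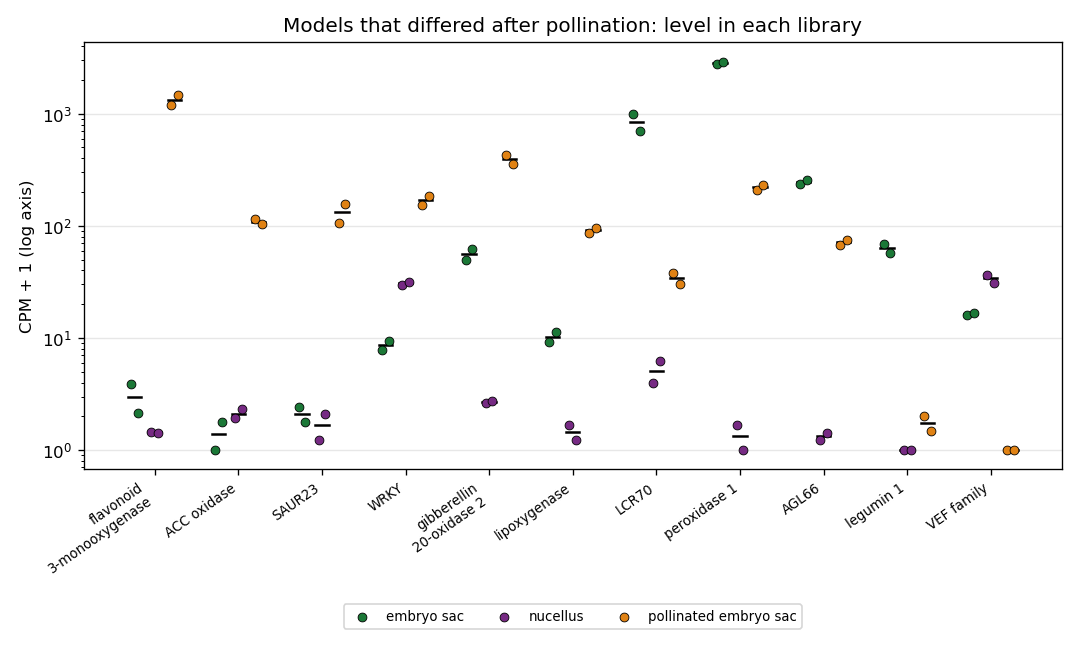
Level of 11 models that differed after pollination in each library, as CPM + 1 on a log axis. Points are libraries and black bars are means of 2 libraries. The first 6 models were higher and the last 5 lower in both pollinated libraries than in both unpollinated embryo sac libraries.

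Further large rises were seen in SAUR23 (GRMZM2G365188_T01), an auxin-responsive gene, by 6.84 ± 0.31 to 131 ± 36.1 CPM, and in peroxidase 72 (GRMZM2G089982_T01) by 5.50 ± 0.30. A VQ motif protein (AC203294.3_FGT012) was at least 35.1-fold higher, and a phospholipid transfer protein (GRMZM2G010868_T01) had a ratio of 78.6 (21.3 to 657). B12D protein (GRMZM2G045155_T02), 1 of 2 models of its gene, was at least 14.0-fold higher. This model alone does not show whether the gene as a whole rose. Among models that fell, a VEF family protein (GRMZM2G157422_T01), of a Polycomb-related family, was at least 10.2-fold lower and biopterin transport-related protein BT1 (GRMZM2G145886_T01) at least 10.5-fold lower. Legumin 1 (GRMZM2G174883_T01), a storage protein, fell from 62.3 ± 8.33 CPM with an unpollinated to pollinated ratio of 83.6, callose synthase 9-like (GRMZM2G331861_T01) with a ratio of 151, CYP714B3 (GRMZM2G106408_T01) with a ratio of 73.1 and aconitase2 (GRMZM2G364988_T03), 1 of 4 models of its gene, with a ratio of 48.3. Their pollinated libraries held 1 to 3 reads in all, so counting intervals of the ratios were wide: 26.7 to 5975 for callose synthase 9-like, 28.4 to 408 for legumin 1, 12.8 to 2914 for CYP714B3 and 13.1 to 403 for aconitase2. On leaving out 1 library, the fitted log2 change ranged from -9.96 to -6.09 for callose synthase 9-like, from -8.91 to -5.10 for CYP714B3, from -9.32 to -4.57 for aconitase2 and from 7.07 to 11.44 for ACC oxidase. Cysteine proteinase 2 (GRMZM5G820822_T01) fell by 2.92 ± 0.19 and beta-fructofuranosidase 1 (GRMZM2G089836_T01), 1 of 2 models of its gene, by 2.39 ± 0.12. Cysteine protease 1 (GRMZM2G340065_T01) rose by 1.02 ± 0.10, which became 0.96 without embryo sac replicate 2 and 0.84 with total count scaling, below the fold threshold.

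Pollen and pollen tube models were measured as markers of another cell type, with 5 of 14 higher and 2 lower (camera adjusted p = 0.23), also when adjusted over the list alone. An anther-specific proline-rich protein (GRMZM2G045215_T01), on the list through the search term anther-specific, rose by 4.44 ± 0.35 to 44.9 ± 2.56 CPM. Models of this description also had reads without pollination, so this rise alone does not show pollen RNA. GRMZM2G105189_T01 stood at 7.68 ± 1.70 CPM in unpollinated embryo sac. Another model so described (GRMZM2G099802_T03), 1 of 2 models of its gene, stood at 4.01 ± 1.36 CPM in unpollinated embryo sac and 6.15 ± 1.35 in nucellus. It had no read after pollination, at least 2.68-fold lower than in unpollinated embryo sac. Exopolygalacturonase, pollen allergen and Expansin-B11 models together reached 9.71 CPM in pollinated and 2.22 CPM in unpollinated embryo sacs, a ratio of 4.40 (2.26 to 9.24). Other lists not past the camera test had 1 higher and 4 lower of 6 for nucellus degeneration and proteolysis (adjusted p = 0.228), 1 and 4 of 11 for sugar transport and sucrose cleavage (adjusted p = 0.272), 6 and 2 of 16 for integument, epidermis and vascular tissue (adjusted p = 0.0747), 2 and 11 of 28 for transposable elements (adjusted p = 0.211), 1 and 5 of 19 for MADS-box factors (adjusted p = 0.213) and 6 and 5 of 47 for histones (adjusted p = 0.098). In these 6 lists the counts adjusted over the list alone were equal. The remaining tested lists had camera adjusted p-values of 0.098 to 0.854, with a median above and a mean below 0 for storage proteins (0.43 and -0.41), proteasome, ubiquitin and F-box (0.21 and -0.10), receptor-like kinases (0.13 and -0.07), peroxidases (0.03 and -0.02), heat shock proteins (0.01 and -0.15) and DNA replication and cell cycle (0.003 and -0.28). The signs were the other way round for lipid transfer proteins (-0.003 and 0.82), and auxin had a median of -0.08 and a mean of 0.00.

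**Figure D4:**
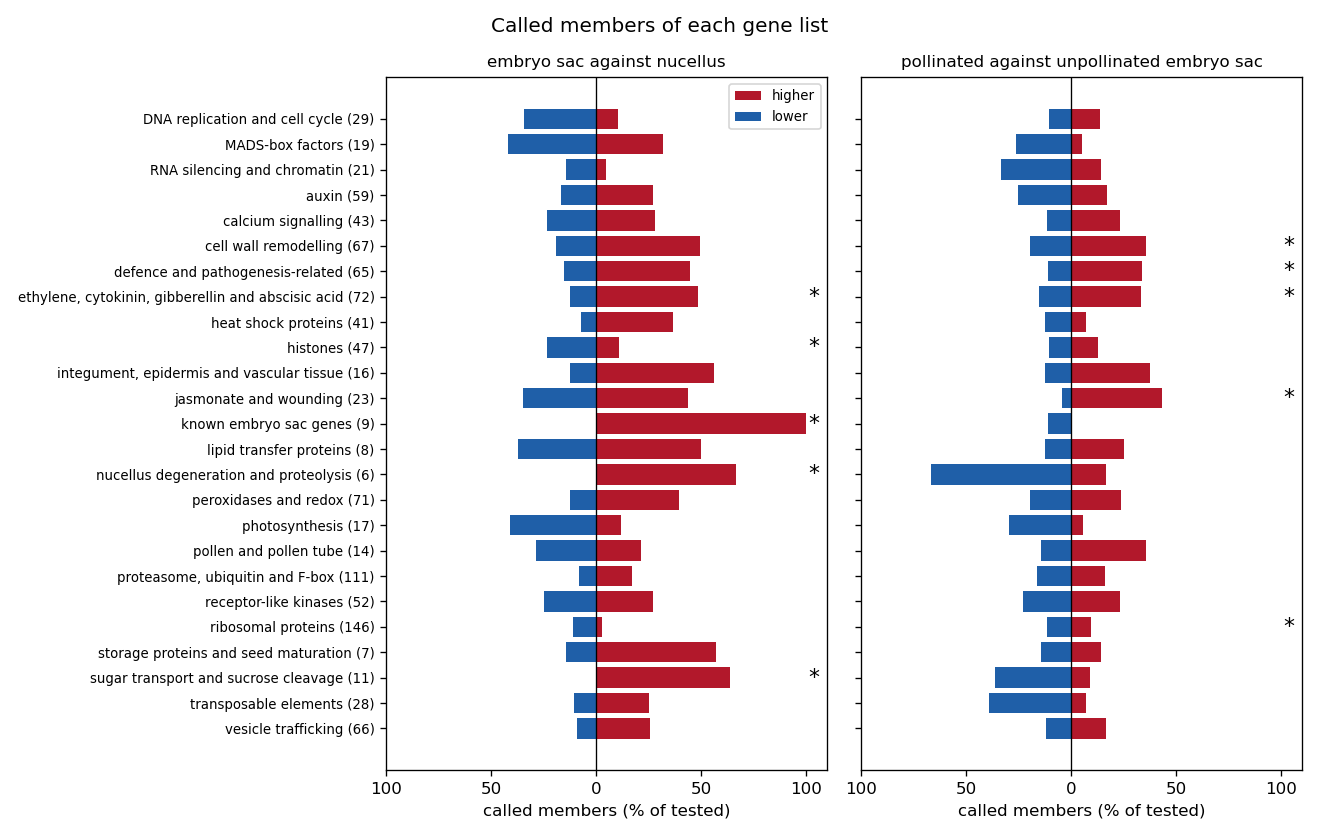
Called members of the 25 tested gene lists, as percent of tested members (number in brackets), with higher models to the right of 0 and lower models to the left. The left panel compares embryo sac with nucellus and the right panel pollinated with unpollinated embryo sac; an asterisk marks a camera adjusted p under 0.05, reached by 5 lists in each panel.

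In all, 2444 models of 2433 genes were higher after pollination and 3646 models of 3442 genes were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Higher calls made up 40.1%, against 30.6% with total count scaling (1928 higher and 4374 lower) and 31.2% with limma on log2(RPKM + 1) (1885 and 4150). The falls were tied to the number of models per gene: 16.6% of tested models of genes with 1 model were lower, against 25.3% of those of genes with several.

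Embryo sac enriched models that also changed after pollination were counted across both comparisons. MEG1, LCR70, peroxidase 1 and AGL66 were among the 814 that were higher in the embryo sac than in nucellus and then fell. Cytokinin dehydrogenase 4, 1 of 3 models of its gene, stood at 109 ± 10.9 CPM in embryo sac and 236 ± 1.73 after pollination, and was among the 915 enriched models that rose. Independent lists would share 845 falling and 567 rising models, while simulated data without any change gave 0 shared calls over 20 datasets, a value that says little since those data held only 0.15 and 0.1 calls per comparison on average. Noise in the shared embryo sac libraries would favour falls over rises among enriched models, so both counts carry it in opposite directions. Falls outnumbered rises with total count scaling (698 and 564), limma on log2(RPKM + 1) (722 and 465) and only the 2 groups compared (862 and 637). The place of the falls against independent lists also depended on the setting. They lay below that value in the main fit and above it with limma on log2(RPKM + 1) (722 against 552) and only the 2 groups compared (862 against 660).

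Pollinated embryo sac was compared with nucellus by counts and lists. All 9 known embryo sac models were higher (camera adjusted p = 4.42e-05, and adjusted p = 0.281 with an estimated correlation). So were 38 of 67 cell wall models with 11 lower (adjusted p = 0.000128), 39 of 65 defence models with 6 lower (adjusted p = 0.000131) and 45 of 72 hormone models with 13 lower (adjusted p = 0.000131), each with adjusted p = 0.113 with an estimated correlation. Peroxidases and redox had 31 of 71 higher and 12 lower (adjusted p = 0.0388, and adjusted p = 0.293 with an estimated correlation). Jasmonate and wounding had 13 of 23 higher and 5 lower (adjusted p = 0.041) and heat shock proteins 20 of 41 and 5 lower (adjusted p = 0.0444), both with adjusted p = 0.281 with an estimated correlation. Counts adjusted over the list alone were equal for these 7 lists, and the median of the peroxidase list turned from 0.61 to -0.31 with total count scaling. In all, 5132 models were higher and 5268 lower, and higher calls made up 49.4%, against 26.0% with total count scaling (3249 and 9250) and 25.2% with limma on log2(RPKM + 1) (3572 and 10609).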

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

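Total count scaling, counts summed per gene, genes with 1 model only and the lists as first matched were chosen after seeing the data. Of 86 log2 changes of named models, the 1 that reversed was that of the EBE protein (GRMZM2G129157_T01, pollinated against unpollinated embryo sac), from 0.15 to -0.027 with total count scaling, -0.021 with limma on log2(RPKM + 1), -0.021 with its no filter form, and -0.022 with limma on log2(RPKM + 0.1), all uncalled. Over all settings 1425 values kept direction and side of the threshold, 7 values of GRMZM2G340065_T01 went under the fold threshold, and 6 passed with adjusted p alone. Most of these models were named for a large change or a small p, so the tally does not describe the called models as a whole. With limma on log2(RPKM + 1), models lower in embryo sac than nucellus numbered 7553 and models lower in pollinated embryo sac than nucellus 10609, with no filter 7588 and 10864, and with log2(RPKM + 0.1) 7112 and 10902. With total count scaling these were 7463 and 9250, models higher in pollinated embryo sac than nucellus 3249, and embryo sac enriched models that rose after pollination 564. Adjusted p alone gave 5156 models lower in embryo sac than nucellus and 4577 higher in pollinated than unpollinated embryo sac. Genes with 1 model only, fewer models by construction, gave 1973 models lower in embryo sac than nucellus, 2301 lower in pollinated than unpollinated embryo sac and 3297 lower in pollinated embryo sac than nucellus. A count of similar size, here or on leaving out 1 library, does not mean that the same models were called. Of models called lower in embryo sac than nucellus and lower after pollination, DESeq2 called 69.5% and 68.2% again. Of the higher calls it kept 87.3% and 83.5%. The limma fit on log2(RPKM + 1) kept 63% and 66% of the higher and 99.4% and 87.5% of the lower calls. DESeq2 gave 521 embryo sac enriched models that fell after pollination. Those that rose numbered 465 with limma on log2(RPKM + 1), 445 with no filter and 437 with log2(RPKM + 0.1), and with adjusted p alone 1651 fell and 2038 rose. An RPKM of at least 0.1 gave 27104 models detected in embryo sac, and of at least 5 gave 10735, with 12301 in nucellus and 9862 in pollinated embryo sac. With an estimated correlation 0 lists passed in each of the 3 comparisons, and with fry, which does not compare a list with other genes, 19, 17 and 21. For pollinated against unpollinated embryo sac, the estimate was -0.0039 for the jasmonate, -0.00186 for the defence, -0.00232 for the hormone and -0.00582 for the cell wall list. All of these lie under the preset 0.01, so a higher correlation does not account for the loss of these lists. For ribosomal proteins it was 0.0281. The cause of these shifts was not tested. Leaving out 1 library kept the counts of called models, and of enriched models that fell or rose, within 1.5 times; the lone library left was assumed to vary like the other groups. The replicate numbers share only a number: their deviations correlated at -0.0194, 0.0165 and 0.00359, and with the replicate block the calls were 4336 and 2963, 2416 and 3544, and 5104 and 5190. Depth limits changes of models below about 1.52 CPM, the floor of the shallowest library.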

Other observations

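The gene ontology terms and the models named in this paragraph were chosen after seeing the data. Of 26 tested models annotated to trehalose metabolism, 16 were higher in embryo sac than in nucellus (Fisher's exact test, BH adjusted p = 0.000683), among them a trehalose-phosphate phosphatase (GRMZM2G178546_T01) at 167 ± 12.9 against 8.91 ± 0.271 CPM. Glucan biosynthesis had 24 of 42 models higher (Fisher's exact test, BH adjusted p = 5.4e-05), and cellulose synthase10 (GRMZM2G445905_T03) was higher by 3.22 ± 0.17 on the log2 scale. In the other direction, 36 of 75 models of microtubule-based processes were lower in the embryo sac (Fisher's exact test, BH adjusted p = 7.35e-09), with kinesin-4 (GRMZM5G817395_T02) at -1.40 ± 0.16 and kinesin-1 (GRMZM2G114861_T01) at -1.25 ± 0.14. Hormone-mediated signaling also pointed down, with 27 of 73 models lower and 8 higher (Fisher's exact test, BH adjusted p = 0.000425), opposite to the hormone list built from descriptions. After pollination, 13 of 18 models annotated to L-phenylalanine metabolism rose (Fisher's exact test, BH adjusted p = 2.97e-06), where phenylalanine ammonia-lyase (GRMZM2G118345_T01), which opens the phenylpropanoid pathway, rose by 4.16 ± 0.24 (3.70 to 4.80 on leaving out 1 library). A model of the same term without an informative description (GRMZM2G334660_T01) rose from 2 and 2 reads to 1329 and 1344. The model opr7 (GRMZM2G148281_T01), whose symbol stands for an oxophytodienoate reductase, is 1 of 2 models of its gene and rose by 1.46 ± 0.20. Fatty acid biosynthesis had 11 of 23 models higher (Fisher's exact test, BH adjusted p = 0.004), and cytoskeleton organization 15 of 32 lower (Fisher's exact test, BH adjusted p = 0.0107).

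Of the tests that follow, those of counting in genes with several models as a cause of the falls, of length as the whole cause, of nucellar RNA in either direction and of pollen tube RNA, and the comparison of annotation text, were chosen after the result was seen, and those of the shortest models and of the number of models listed before. For nucellar RNA a first criterion, at least 10 abundant nucellar models allowing a share under 5%, had given 6 such models for unpollinated and 12 for pollinated libraries, and was then replaced. The limit used below is the share that 10 of 1702 models with at least 100 CPM in nucellus do not exceed at the upper end of their 95% interval, taking nucellus as it was before pollination.

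More models fell than rose after pollination. Counted per gene, the median log2 change was 0.10 in genes with 1 model and -0.76 in genes with 4 or more, a difference of -0.863 (0.257 for nucellus over embryo sac), and the pollinated tables carry another version of the GO text, so a difference in how those libraries were counted may account for part of the falls, though pollination and processing are confounded. Falls were not confined to genes with several listed models, since 16.6% of models of genes with 1 listed model fell. This does not exclude such counting as the whole cause, since genes with 1 listed model may have others without a read. An example is GRMZM2G118250, listed only by its model T06. Length as the whole cause is argued against by the 14.0% that fell even in the 20% of those models, ordered by length, with the fewest falls. Against loss of carried-over nucellar RNA stand the 99.9% of fallen models that need a nucellar share above the limit of 7.81%. A processing difference that also reached 1-model genes cannot be told apart from pollination. Length cannot be told apart from other causes for part of the falls: 22.2% of the shortest 20% fell and 15.8% of the longest, and the test written before looked only for falls confined to long models. A response to pollination stays open for the falls in 1-model genes.

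The models that rose included hormone and defence genes. For 99.9% of them nucellus as it was before pollination would need a share above the limit of 4.43%, but no nucellus was sampled after pollination, so transcripts induced there and carried over cannot be told apart from a response of the embryo sac. The same holds for RNA of the pollen tube: pollen marker models summed to 9.71 CPM against 2.22 CPM before pollination, and their level in pollen was not measured here. Each of these may contribute.

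Fewer models were listed in the pollinated libraries. Thinned to the lowest total, the unpollinated libraries still listed 12.5% more models, which argues against depth, and 13.3% more without the 10 most abundant models of each library, which argues against a few models taking the reads. Over genes with 1 listed model the excess was 4.86%, against 25.5% over models of genes with several, so counting of such genes may account for much of the difference. What remains may come from a narrower transcriptome after pollination or from counting in genes whose other models drew no read. These cannot be told apart.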
